A study of Xenopus laevis with 3 samples.

How the data were processed

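Each of the 3 samples was a 2-channel microarray on which RNA of Xenopus laevis embryos treated with TTNPB (channel 1, per the labels) was hybridised against RNA of embryos treated with AGN193109 (channel 2, per the labels). The labels put the 3 arrays in 1 group and do not say whether they came from separate batches of embryos, so the p-values measure only the spread between these arrays, which may be technical. RNA came from whole embryos and was enriched for poly A, per the labels. The protocol there also mentions ethanol-treated embryos, but none of the 3 arrays carried them in a channel. The dyes, the scanner, the image analysis, the background correction and the normalisation method are not given in the sources used here.

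The authors deposited 1 table with a log ratio for each of 20799 rows on each of the 3 arrays, without missing values and without intensities. Of these rows, 20618 have clone names made of a plate number, a row letter and a column number, from 55 plates of up to 384 wells, and 181 have names beginning with Contr. The log base and the direction of the ratio are not stated. The base was worked out from the values. Within an array, 171 values recur exactly, summed over the 3 arrays. Where each was compared with the most frequent one, 144 of 168 differences fitted the mean of 2 natural log ratios of small whole numbers (up to 200, relative tolerance 2.5e-09), while 2 fitted a single natural log ratio and 0 a log2 or log10 ratio. A mean of 2 ratios gives products of whole numbers, in which primes are rare. Primes made up 5.6% to 7.7% of the recovered whole numbers between 200 and 600, per array. In simulated values they made up 8.5% for means of 2 ratios and 26.5% for square roots of a single ratio. The range of intensities simulated for means of 2 was widened after a first simulation, with a narrow range, gave fewer primes than the data. The deposited values were therefore read as a natural log ratio averaged over 2 readings, plus 1 constant per array set by the authors, and were divided by the natural log of 2 to give log2 ratios. Whether the 2 readings were spots on 1 array or hybridisations with exchanged dyes stays unknown, as does the direction. Signs are therefore given as deposited, and "positive" and "negative" do not say which treatment was higher. The deposited medians were -0.042, -0.025 and -0.081 in natural log units on arrays 1, 2 and 3.

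The same property was used to mark faint features, on the reading that only low intensities give ratios of small whole numbers; no intensity was used here to check it. A feature was called faint where its value resolved to whole numbers of at most 600. This applied to 1020, 1320 and 1032 rows on arrays 1, 2 and 3, against 5, 9 and 13 after small random shifts of the values. Moderately dim features are missed by this rule, and so are most features with a large ratio, since both channels must be low.

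The 181 Contr features were left out as controls. The plan had been to use every feature with 3 values, and the choice to leave these out was made after a first fit of all features. The log2 ratios of the clones were centred on each array's median, and the mean of the 3 arrays was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes) and Benjamini-Hochberg adjustment over the 20618 clones, with a threshold of 0.05. On simulated data with 200 of 20618 clones changed, this test recovered 22.7% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, and 5.5% of its calls were false. The simulated share of changed clones was far below the share called in the data, which makes the adjusted threshold stricter there, so these recoveries do not give the reach of the test on the data. The simulated noise was independent between clones, without shifts by plate, row, column or faint signal. The 5.5% therefore does not give the share of false calls in the data. The number of arrays limits the precision: the median standard error of a clone's mean log2 ratio was 0.129.

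The test, the gene lists, the rule for named items and most alternatives were set before the data were examined. Nothing used here pairs the clone names with genes: 0 of them occurred in a table of 44456 Xenopus laevis genes (assembly v10.1). The planned gene-level test and the 22 gene lists were therefore not run. The rule for named items then left the 2 clones with the largest mean ratio on each side among those past the threshold with 1 sign on all 3 arrays. Alternatives covered centring, scaling to equal median absolute values (normalizeMedianAbsValues, in place of the planned limma function, which divides by medians that are 0 after centring), quantile normalisation, the variance model, the thresholds and leaving out each array. Chosen after seeing the data were the removal of source-plate position (plate, row and column medians subtracted on each array in 5 rounds), the exclusion of faint clones, the inclusion of the Contr features, a test against 1.5-fold and a reading of the values as log2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the whole-number search and the plots.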

Results

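Retinoic acid receptors (RARs) are ligand-activated transcription factors with known roles in patterning the vertebrate embryo. The series asked which genes in the Xenopus neurula respond to them. Embryos of Xenopus laevis, the African clawed frog, were exposed from stage 7, a blastula stage, to stage 11, a gastrula stage, to 1e-06 M TTNPB, a synthetic RAR agonist, or to 1e-06 M AGN193109, an RAR antagonist. They were held at 16 to 19 °C, in dishes of 25. The stage at which RNA was taken is not stated. RNA of whole embryos was compared directly on 3 clone arrays, with the agonist-treated embryos in one channel and the antagonist-treated embryos in the other. Each array gave a ratio for 20618 clones. Agonist and antagonist act in opposite senses on the receptor, and with no vehicle-treated embryos on the arrays a ratio does not separate a response to one from a response to the other.

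Many clones had a ratio of agonist-treated to antagonist-treated embryos, in one sense or the other, that departed from the array median on all 3 arrays. Of 20618 clones, 4057 (19.7%) passed limma's moderated test at an adjusted p under 0.05. Of these, 1829 were positive and 2228 negative in the deposited sign, and 4021 had 1 sign on all 3 arrays. The deposited values do not state which channel was the numerator, so neither side was assigned to the agonist. At an unadjusted p under 0.05, 6880 clones passed, where chance alone would give 1031.

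Most differences were small and a few were large on both sides. The median size among clones past the threshold was 0.54 on the log2 scale on the positive side, or 1.46-fold, and 0.56 on the negative side, or 1.48-fold. The smallest difference past the threshold was 0.37 on either side. A mean difference of at least 2-fold with 1 sign on all 3 arrays was reached by 185 positive and 215 negative clones, at least 4-fold by 27 and 27, and at least 8-fold by 8 and 8. A test against 1.5-fold, rather than against no difference, left 256 clones, of which 140 were positive and 116 negative.

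The largest positive mean ratio belonged to clone XL044a07, from plate 44, well row a, column 7. Its log2 ratio was 4.02 ± 0.09 (SD, n = 3), a 16.2-fold difference with a 95% interval of 3.76 to 4.29 on the log2 scale and a limma adjusted p of 4.09e-10. Clone XL036f08 followed with a log2 ratio of 3.63 ± 0.35 (SD, n = 3), or 12.4-fold (limma adjusted p = 1.93e-09). On the negative side, clone XL018f06 had the largest mean, at -4.07 ± 0.97 (SD, n = 3), a 16.7-fold difference with an interval of -4.6 to -3.54 and a limma adjusted p of 1.64e-07. Clone XL044h18 had a log2 ratio of -3.37 ± 0.88 (SD, n = 3), or 10.4-fold (limma adjusted p = 3.89e-07). The negative pair varied more between arrays than the positive pair: XL018f06 read -5.08, -3.98 and -3.14 on arrays 1, 2 and 3, and XL044a07 read 4.1, 4.04 and 3.92. The intervals and p-values rest mostly on variance pooled across clones, which supplied 11.8 of the 13.8 degrees of freedom. They are therefore narrower than the own spread of the negative pair would give. The interval of XL018f06 leaves out its values on arrays 1 and 3. No clone of these 4 was marked as faint on any array, but the mark seldom reaches ratios this large. Their genes, genomic positions and annotations were not analysed here, since no table used here links the clone names to genes.

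**Figure D1:**
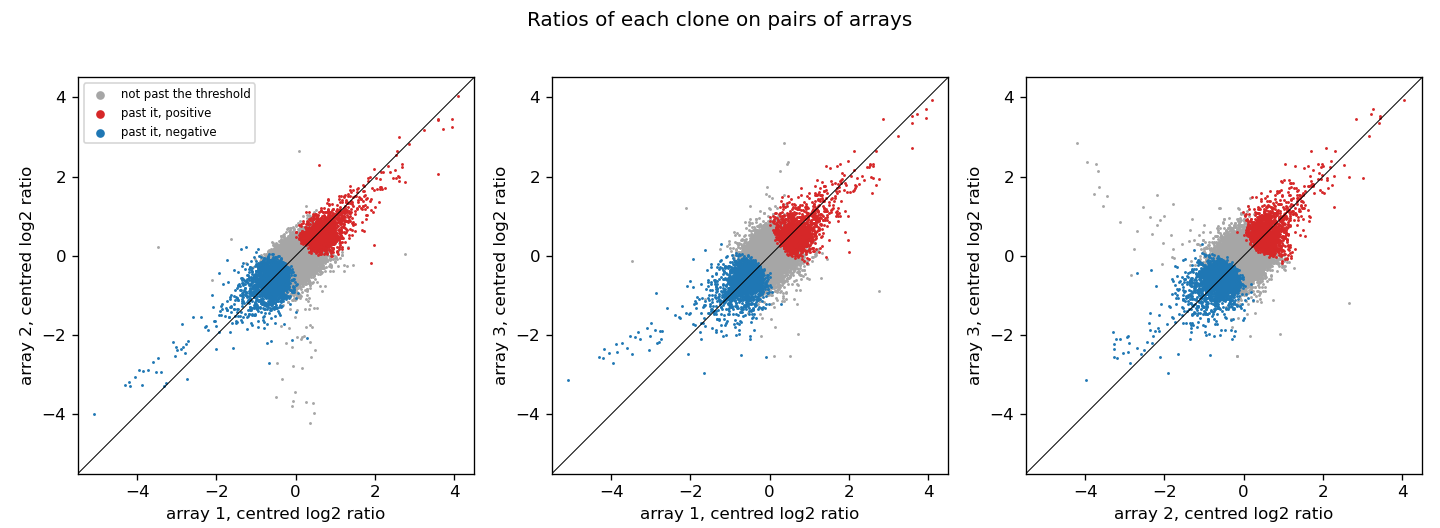
Centred log2 ratio of each of the 20618 clones on arrays 1 and 2 (left), 1 and 3 (middle) and 2 and 3 (right), one point per clone, with the line of equal ratios. Clones past the limma threshold are red (1829 positive) or blue (2228 negative), the rest grey; at 4-fold or more most ratios are smaller on array 3 than on array 1 on both sides, in 23 of 27 positive and 25 of 27 negative clones (median array 3 to array 1 ratio 0.907 positive and 0.644 negative), while a set of grey clones is low on array 2 and high on array 3.

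The 3 arrays ran in the same sense. Across clones, Pearson's r was 0.692 between arrays 1 and 2, 0.648 between arrays 1 and 3 and 0.554 between arrays 2 and 3. The clones are not independent replicates, and no p-value was attached. Spearman's rho was 0.617, 0.542 and 0.484 in the same order. The SDs of the ratios were 0.441, 0.432 and 0.428 on the log2 scale for arrays 1, 2 and 3. The SD of the difference between arrays was 0.342, 0.365 and 0.406, so no pair held the same values. Among the 16561 clones not past the threshold, r was 0.314, 0.216 and 0.072, and the median absolute log2 ratio was 0.15. These clones were set apart by a small mean ratio on the same arrays, which by itself lowers r. The 3 values therefore do not measure the agreement outside the calls. Between arrays, a clone's ratio had a median SD of 0.194. The 95% interval of a clone's mean reached a median of 0.28 to either side.

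The number past the threshold depended on pooling the variance across clones and on the arrays used, most of all on array 1. Without moderation of the variances, 0 clones passed the adjusted threshold and 4088 had an unadjusted p under 0.05. Limma left 1410 clones past the threshold without array 1, 2974 without array 2 and 3796 without array 3. With the values as deposited rather than centred, 1329 clones were positive and 3081 negative, so the balance of the sides rested on where 0 was placed.

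Clones with faint signal lay mostly on the negative side. Clones that were faint on at least 1 array numbered 2306, or 11.2% of all clones, and 776 of them (33.7%) passed the threshold, against 3281 of 18312 (17.9%) of the others. Among the calls, 90.1% were negative in faint clones and 46.6% in the others. The median log2 ratio of faint clones was -0.24, -0.16 and -0.28 on arrays 1, 2 and 3, against 0.02, 0.02 and 0.03 for the others. At 2-fold or more, 91 of the 215 negative clones were faint, compared with 8 of the 185 positive clones.

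**Figure D2:**
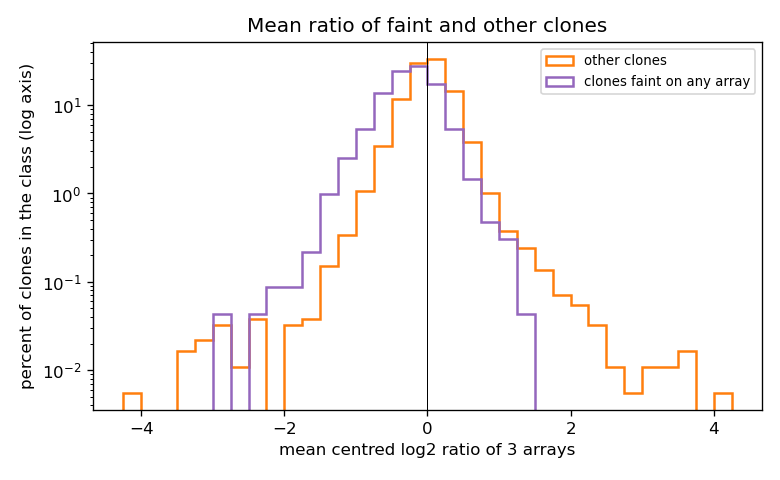
Distribution of the mean centred log2 ratio of 3 arrays (x axis) in clones faint on any array (purple, 2306 clones) and in the other clones (orange, 18312), as percent of each class on a log axis. The faint clones are shifted to the negative side.

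Position on the source plate was visible in the ratios. Well row accounted for 4% of the variance on array 1, 22.3% on array 2 and 0.6% on array 3, and well column for 1.5%, 0.4% and 7.3%. On array 2 the row medians ranged from -0.4 in row e to 0.29 in row i. Source plate accounted for 3.1%, 1.9% and 3.5% of the variance, and plate medians went together on the 3 arrays across the 55 plates (r = 0.83, 0.9 and 0.72 for arrays 1 and 2, 1 and 3, and 2 and 3; plates are not independent samples). The mean of the 3 medians was lowest on plate 1, at -0.17, where 96 negative and 18 positive clones passed the threshold, and highest on plate 49, at 0.1, with 26 negative and 61 positive.

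**Figure D3:**
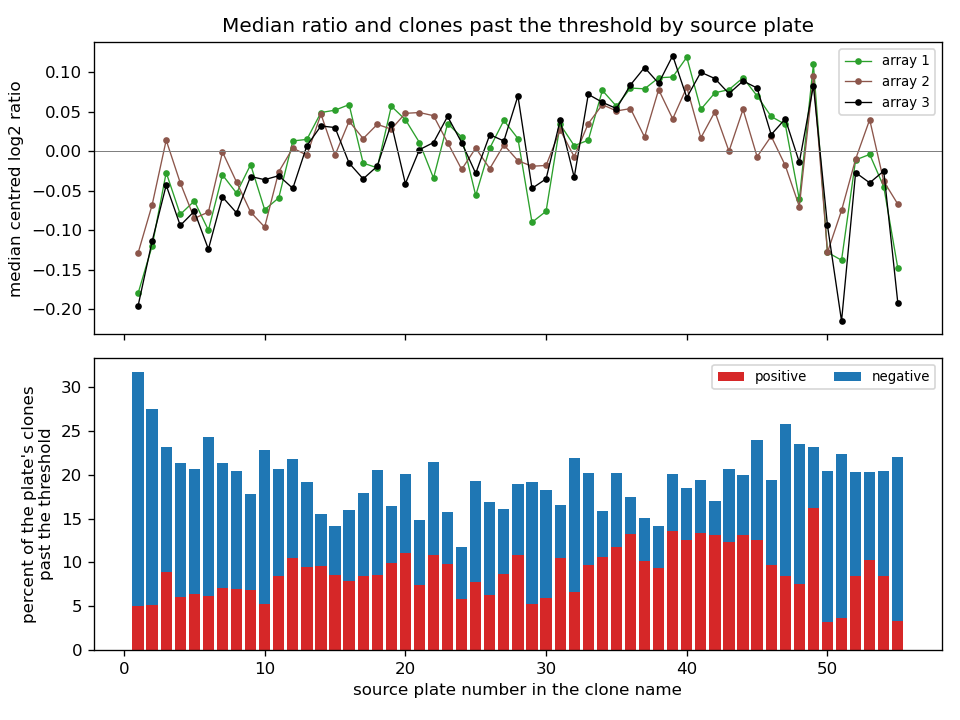
Upper panel, median centred log2 ratio of the clones of each of the 55 source plates on arrays 1 (green), 2 (brown) and 3 (black); lower panel, percent of each plate's clones past the threshold, positive in red and negative in blue, stacked. The 3 arrays follow each other from plate to plate, and plates 1, 50, 51 and 55 have the lowest medians, with 3.2% to 5% of their clones past the threshold on the positive side.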

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

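Chosen after the data were seen were the position, faint, Contr, 1.5-fold test and log2 alternatives. Of 14 alternatives for the number of clones past the threshold (4057), 10 stayed within 1.5 times of it, up to 5702 at an adjusted p under 0.1. Without moderation of limma's variances 0 clones passed (smallest adjusted p 0.173, 4088 at an unadjusted p under 0.05). A minimum of 1.5-fold left 1783 and limma's test against 1.5-fold 256, both stricter by construction. Leaving out each array in turn gave 1410 (without array 1) to 3796, and kept 34.3%, 65.9% and 75.9% of the original calls without arrays 1, 2 and 3. Each such fit has fewer arrays. The counts rose with the agreement of the pair left, with r of 0.554, 0.648 and 0.692 without arrays 1, 2 and 3. With plate, row and column medians removed, r was 0.745 for arrays 1 and 2, 0.64 for arrays 1 and 3 and 0.661 for arrays 2 and 3. Arrays 2 and 3 were then no longer the pair that agreed least, so that rank went with position on the source plate. Other causes were not tested. Without centring, 30.1% of calls were positive instead of 45.1%. Equal-spread scaling, quantile normalisation and robust variances kept 99.3%, 99.3% and 98.8% of the original calls. The 400 clones with a 2-fold mean ratio became 1767 at 1.5-fold, 203 where every array had to show 2-fold and 126 with the values read as log2, each by construction. Leaving out 1 array gave 420 to 463, and leaving out faint clones 307. The mean correlation between arrays, 0.631, became 0.554 to 0.692 with 1 array left out. The 4 named clones kept their sign under the 9 alternatives run on them. Their choice by the largest means with 1 sign on all 3 arrays left no room for another outcome. They lost the threshold in 1 alternative, the fit without moderation. Requiring a value on 2 arrays moved nothing, since none was missing. Gene-level alternatives and gene lists were not run, for want of gene names. No paired analysis was possible because the arrays form 1 group. Signal over background was not measured, since no intensity was used here.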

Other observations

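Chosen after the results were seen were all tests of the clones that spanned 8-fold, all tests at 4-fold, the scale test at 2-fold and the count left without faint clones; the other tests were set before their results.

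A small set of clones gave opposite ratios on different arrays. In 21 clones the 3 arrays spanned 8-fold or more, 0 of which passed the threshold, and 16 of them, from 14 source plates, were lowest on array 2 (median log2 ratio -3.28), between on array 1 (0.23) and highest on array 3 (1.41). Spot failures with equal chances for the 6 orders are argued against by the 16 of 21 in 1 order (exact binomial test, one-sided, p = 1.85e-08 after correction for 6 orders). Equal chances were not a given, since over all clones arrays 2 and 3 differed most (SD of the difference 0.406, against 0.342 and 0.365). The p also counts the clones as independent, though some may share a transcript, so it speaks only against equal chances. Failures that run low on array 2 and high on array 3 stay open. Of the 12 clones 2-fold lower on array 2 and 2-fold higher on array 3 than on array 1, where independence gives 0.674, 11 were among the 21. This count is therefore no separate evidence. Shifts shared by a plate, row or column are too small to be the cause, at 0.34 or less on the log2 scale in these clones, and 95.2% still spanned 8-fold without them. Of the 21, 14.3% were marked as faint (upper 95% limit 36.3%), against 11.2% of all clones. The mark needs both channels low and seldom reaches large ratios, but on array 1 these clones had small ratios (median absolute log2 ratio 0.36). This argues against very low signal in both channels of array 1 in most of them. Faint signal on arrays 2 and 3 stays open, as does moderately dim signal, which the mark misses. A few transcripts whose amount differed between the embryos behind the arrays may account for the set, a hypothesis that was not tested because the labels give no batches and the clones have no gene names here.

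The negative ratios were compared between arrays 3 and 1 at 2 sizes, the larger chosen after the smaller had shown no clear difference. At 2-fold or more, the median ratio of the array 3 value to the array 1 value was 0.887 on the negative side (95% bootstrap interval over clones 0.835 to 0.976) and 0.929 on the positive side (0.894 to 0.98), so the sides overlapped, as they did without faint clones (negative 0.844, 0.77 to 0.908) and with position medians removed (negative 0.866, 0.803 to 0.955). At 4-fold or more, with 27 clones a side, it was 0.644 (0.599 to 0.689) against 0.907 (0.872 to 0.936), which argues against 1 scale factor per array, and 0.618 with position medians removed argues against shifts by plate, row or column, while 0.617 without faint clones decides nothing, as 14.8% of the negative clones were marked at this size against 46.3% from 2-fold to under 4-fold. From 2-fold to under 4-fold, the negative ratio was 0.951 (0.881 to 1.018) and the positive 0.936 (0.9 to 1.007), so the difference, at a size picked on the same data, is a hypothesis about the largest ratios alone, and clones of 1 transcript would make the intervals too narrow. At 4-fold or more the negative medians were -3.32, -2.88 and -2.21 on arrays 1, 2 and 3, and the positive medians 2.61, 2.23 and 2.3. Array 1 thus read largest on both sides, and the ratio alone does not tell whether array 1 or array 3 stood apart. A channel close to background on array 3, or a few transcripts that responded less there, may produce the difference between the sides. Neither was settled here.

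The number of calls was weighed against chance, position and faint signal. Turning the sign of 1 array at a time gave 0 clones past limma's threshold each time, against 4057 as deposited. At an unadjusted limma p under 0.05 the turned fits gave 44, 105 and 223 clones, fewer than the 1031 of chance alone. Because the arrays correlate, turning 1 of them makes shared ratios into spread. The fall therefore follows from their correlation and decides nothing about chance. The deposited signs were the 1 of 4 sign patterns with that many calls, and 4 patterns are too few for a share under 0.05. Position as the whole cause is argued against by the 80.2% of calls kept on their side when its medians were removed. That fit called 4496 clones, of which 3254 were original calls, so position did change which clones were called. The clones marked as faint as the whole cause are argued against by the 3281 of 4057 calls that lay outside them. The fit without the marked clones left 82.2% of the count and kept 77% of the original calls, which followed largely from that number. Dim clones that the mark misses were not tested. Faint clones were called 1.88 times as often as the others (95% interval 1.76 to 2, with clones counted as independent). The excess lay on the negative side, with 699 of 2306 faint clones against 1529 of 18312 others. On the positive side the rate was lower in faint clones, with 77 calls against 1752 in the others. Faint signal may thus add to the negative calls. The faint clones lay lower as a set (median log2 ratio -0.23 against 0.02), which by itself lowers their rate of positive calls. That lower rate therefore decides nothing about an effect of signal strength on the positive calls. A dye effect of single clones shared by the 3 arrays and a difference between agonist and antagonist, the contrast of the design, stay open, as the dyes are not stated and no test here separates them.

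The SD of the 55 plate medians was 0.0628 on the log2 scale and 0.0561, or 89.4% of it, without faint clones, where a fall to under 50% had been set as the mark of faint signal as its source. Plates with more faint clones nonetheless had lower medians (Spearman's rho -0.75 across the 55 plates, which are not independent samples), and plates 1, 50, 51 and 55, with the lowest medians, had 23.1%, 13.5%, 17.3% and 17.9% faint clones against 11.2% of all clones, though plate 49, with the highest, had 12.2%. The clones marked as faint thus did not carry most of the spread. They made up 3.6% (plate 37) to 23.1% (plate 1) of a plate, with a median log2 ratio of -0.23 against 0.02 for the others. Leaving out so few could hardly bring the SD under 50%, so the 89.4% decides little about faint signal as the source. Dim clones that the marking misses were not tested.

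The 181 Contr features, whose content the names do not state, had median log2 ratios, relative to the clones, of -0.24, -0.41 and -0.13 on arrays 1, 2 and 3. The 45 from columns 4, 8, 12, 16, 20 and 24 read -0.15, 1.02 and 0.08, the 66 from columns 2, 6, 10, 14, 18 and 22 read -0.28, -0.56 and -0.5, and the 68 from columns 3, 7, 11, 15, 19 and 23 read -0.25, -0.56 and 0.09. In a fit that included them, 56 of the 181 passed limma's threshold, 53 of them negative, with 3, 39 and 13 of the 56 in these classes. The planned check of the direction of the ratio on genes that retinoic acid is known to induce was not run, since the clones could not be named.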
